A study of Mus musculus with 20 samples.

How the data were processed

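RNA was measured in CD8+ T cells sorted from MC38 tumours on day 4 after treatment, in 4 groups of 5 libraries (Control, Pembrolizumab, ABL503 and Combination). Tumours had reached a mean volume of 150 to 200 mm3 when the mice were randomised. Libraries were made with SMART-Seq v4, a kit that copies full-length cDNA from few cells, per the labels. Per the submitters' processing notes, reads were aligned with HISAT2 and quantified with StringTie on GRCm38 (mm10), and no version or annotation release is given. The deposited values are FPKM, which is inferred: the table names no unit, its values are not whole numbers, and its column sums differ between libraries. No scaling between libraries is stated for the deposited table. The table held 45777 gene symbols without repeats, of which 31149 were above 0 in at least 1 library. Of all symbols, 40686 (88.9%) were found in the RefSeq gene models of GRCm38 used for positions. Read counts and sequencing depth are not given, so the precision of a value rests on the spread between the 5 libraries.

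All 20 libraries were used. Genes with at least 1 FPKM in at least 5 libraries were kept, which left 11794. Values were analysed as log2(FPKM + 1). limma 3.58.1 in R 4.3.3 fitted 1 mean per group with a shared spread (16 residual degrees of freedom) and moderated variances with an intensity trend. The 7 comparisons were the 3 treated groups against Control, the 3 treated groups against each other, and the interaction (Combination minus ABL503) minus (Pembrolizumab minus Control). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and all tests were two-sided. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made summaries and plots.

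Lists of genes, 36 in all, were written before the data were examined, from general knowledge of T-cell states, metabolism, stress and other cell types. They held 685 genes, of which 667 were in the table and 562 were tested. Each list was tested with camera, which compares its members with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry, which tests whether members move on balance in 1 direction. Adjustment was over the lists within a comparison. Of the 96 list results past an adjusted p of 0.05 at the preset correlation, 7 passed with an estimated correlation and 41 passed fry. No list among the 96 had a median, mean and test of different sign.

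Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls per comparison among genes past the threshold with a mean log2(FPKM + 1) of at least 3, leaving out numbered or predicted models, pseudogenes, small RNAs and receptor V, D and J segments. It added up to 4 members with the smallest p of each list described, and a fixed panel that included Cd8a, Cd3e, Tnfrsf9, Pdcd1, Cd274, Gzmb, Prf1, Ifng, Mki67, Tcf7, Havcr2, Tox and Il7r. Genes named outside the rule are said to be so.

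The steps were tested on simulated data with 200 changed genes per comparison. For ABL503 against Control, 46.3% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, with 11 wrong calls among 11794 genes. The right calls at these folds were 31, 53 and 63, beside the 11 wrong ones. Noise was drawn independently for each gene, so correlation between genes was not part of the test. Changed genes came from those with a Control mean log2(FPKM + 1) above 2.

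Alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, array weights, the replicate number as a block, only the groups compared, an adjusted p under 0.1, a minimum absolute log2 change of 1, and leaving out each library in turn. Alternatives added after the data were seen were rescaling each library to an equal sum, leaving out the pair of libraries with the lowest array weights, and covariates for the level of other-cell markers or of immediate early genes. Methods that need read counts were not run, since none are deposited.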

Results

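CD8+ T cells that had infiltrated a tumour were profiled by RNA sequencing on day 4 after the start of treatment. The tumours were MC38, a mouse colon carcinoma line, made to overexpress human PD-L1, and grew in C57BL/6 mice carrying human PD-1, PD-L1 and 4-1BB. The 20 libraries fell into 4 groups of 5: Control, Pembrolizumab, ABL503 and the Combination of both. Pembrolizumab is an antibody that blocks PD-1, and ABL503 a bispecific antibody that binds PD-L1 and 4-1BB. The deposited table gave 1 value per gene symbol for 45777 symbols, judged from the values to be FPKM, which scales fragments by gene length and library size. Column sums ran from 575918 to 654333. The depth of each library is unknown, so no counting interval is given. Changes are differences of log2(FPKM + 1), which understate fold changes of genes with low values. The labels do not say that the 5 libraries of a group came from separate mice, so p-values measure the spread between these samples.

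The libraries carried the markers of the sort. Cd8a, the CD8 alpha chain, stood at 279 ± 46.7 FPKM in Control (SD, n = 5, as for every FPKM mean) and at 377 ± 61 in the Combination, where it was higher by 0.43 (SE 0.11, adjusted p = 0.013). Cd3e of the T-cell receptor complex stood at 248 ± 51.7 and 275 ± 34.3. Cd4 averaged 0.398 FPKM in Control and the collagen gene Col1a1 0.0184. Genes of antigen-presenting cells were above that floor. Cd74, the MHC class II invariant chain, stood at 115 ± 48.8 FPKM in Control, 42.9 ± 18.4 in Pembrolizumab, 121 ± 37.8 in ABL503 and 29.9 ± 11.3 in the Combination. Lyz2, the lysozyme of myeloid cells, stood at 18.8 ± 26.3 in Control and 3.4 ± 4.55 in the Combination. Cd74 is in the rule for named genes, and Cd4, Col1a1 and Lyz2 were chosen after their values were seen. The first principal component of the 500 most variable genes held 17.1% of the variance. Control averaged -12.5 on it (SD 4.54), ABL503 -3.6 (SD 2.54), Pembrolizumab 1.93 (SD 2.19) and the Combination 14.1 (SD 8.66).

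**Figure D1:**
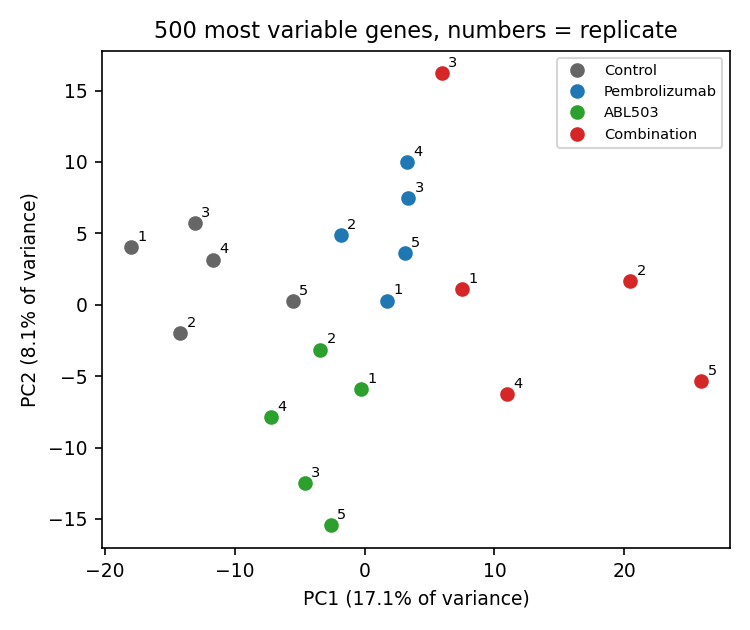
Principal components 1 (x axis) and 2 (y axis) of log2(FPKM + 1) for the 500 most variable genes, each point a library coloured by group and numbered by replicate. The 5 Control libraries sat between -18 and -5.54 on the first component and the 5 Combination libraries between 5.94 and 25.9.

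The comparison of Pembrolizumab with Control asked what PD-1 blockade alone changed in these T cells. Genes of the killing machinery were higher. Prf1, the pore-forming protein perforin, rose from 6.3 ± 2.27 to 33 ± 4.34 FPKM (log2 change 2.27, SE 0.21, adjusted p = 4.93e-06), and Gzmb, the apoptosis-inducing protease granzyme B, from 633 ± 162 to 2246 ± 301 (log2 change 1.86, SE 0.20, adjusted p = 2.30e-05). Tcf7, which encodes the transcription factor TCF1 of stem-like and memory T cells, fell from 36.5 ± 14 to 11.9 ± 5.7 (log2 change -1.61, SE 0.42, adjusted p = 0.028). Tnfrsf9, the gene of the costimulatory receptor 4-1BB, rose from 107 ± 13.6 to 241 ± 38.8 (log2 change 1.15, SE 0.12, adjusted p = 1.11e-05), and Ifng, the cytokine interferon gamma, changed by 0.61 (SE 0.17, adjusted p = 0.034).

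In all, 655 of 11794 tested genes passed, 327 higher and 328 lower. Among genes with a mean log2(FPKM + 1) of at least 3, the limit of the rule for named genes, the 8 largest rises included Prf1 and Gzmb. The others were Serpine2, a secreted serine protease inhibitor (3.41 on the log2 scale), the granzyme F gene Gzmf (3.23) and Zbtb32, a zinc-finger repressor induced in activated lymphocytes (2.52). After these came the hypoxia-responsive mitophagy gene Bnip3 (2.16), Ms4a4a (1.74) and the metallothionein Mt2 (1.62). The 8 largest falls above that limit included Tcf7, Krt83 (-1.64), Cd7 (-1.44) and Id3, an inhibitor of DNA-binding factors kept by memory precursors (-1.43). The others were Cd74 (-1.42), Tsc22d1 (-1.20), Qpct (-1.17) and Cd83 (-1.09). Adjusted p over these 16 ran from 4.93e-06 for Prf1 to 0.028 for Tcf7.

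Among the gene lists, glycolysis and hypoxia genes rose (median log2 change 0.33, camera adjusted p = 4.11e-11, and adjusted p = 0.037 with an estimated correlation). Of 25 tested, 9 rose and 0 fell, or 12 and 0 adjusted over the list alone. Aldoa, an aldolase, changed by 0.91 (SE 0.10, adjusted p = 4.30e-05) and Pgk1, phosphoglycerate kinase, by 0.84 (SE 0.12, adjusted p = 0.00036). Cytotoxic effector molecules rose (median log2 change 0.73, camera adjusted p = 6.58e-09, and adjusted p = 0.012 with an estimated correlation). Of 19 tested, 7 rose and 0 fell, or 12 and 1 adjusted over the list alone. Effector and short-lived effector genes rose too (median log2 change 0.36, camera adjusted p = 2.80e-06, and adjusted p = 0.012 with an estimated correlation). Of 20 tested, 7 rose and 0 fell, or 10 and 2 adjusted over the list alone. Among them were Zeb2, a transcription factor of terminal effectors (1.01, SE 0.16, adjusted p = 0.00098), the NK-type receptor Klrd1 (0.81, SE 0.16, adjusted p = 0.006) and Gzma, granzyme A (1.58, SE 0.34, adjusted p = 0.0095).

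Stem-like, naive and memory genes were lower after pembrolizumab (median log2 change -0.34, camera adjusted p = 0.001, and adjusted p = 0.46 with an estimated correlation). Of 25 tested, 0 rose and 4 fell, or 0 and 7 adjusted over the list alone. The 4 that fell were Tcf7, Id3, Slamf6 (-0.60, SE 0.15, adjusted p = 0.022) and S1pr1, the receptor for exit from tissue (-0.98, SE 0.22, adjusted p = 0.014). Inhibitory receptor and exhaustion genes were mostly higher (median log2 change 0.20, camera adjusted p = 0.0064, and adjusted p = 0.33 with an estimated correlation). Of 21 tested, 3 rose and 1 fell, or 7 and 1 adjusted over the list alone. Havcr2, which encodes TIM-3, led them at 1.0 (SE 0.15, adjusted p = 0.00065). TNF receptor and NF-kB targets were lower (median log2 change -0.19, camera adjusted p = 0.04, and adjusted p = 0.55 with an estimated correlation). Of 24 tested, 1 rose and 6 fell, or 1 and 8 adjusted over the list alone. The survival factor Birc3 gave -0.61 (SE 0.11, adjusted p = 0.0029). Oxidative phosphorylation genes shifted upward (median log2 change 0.14, camera adjusted p = 0.0009, and adjusted p = 0.53 with an estimated correlation), as did those of fatty acid oxidation (median log2 change 0.20, camera adjusted p = 0.04, and adjusted p = 0.36 with an estimated correlation). Mki67, a proliferation marker, gave 0.08 (SE 0.17, adjusted p = 0.87), and Pdcd1, the PD-1 gene, 0.12 (SE 0.24, adjusted p = 0.85). Macrophage and monocyte markers had a median log2 change of -0.20 (adjusted p = 0.59). The fibroblast and stroma list had 1 tested gene, Thy1, which T cells carry too and which rose (0.63 (SE 0.12, adjusted p = 0.0057), and for the list camera adjusted p = 0.033, and adjusted p = 0.13 with an estimated correlation). With the level of other-cell markers as a covariate 2 genes named here no longer passed, with log2 changes before and after of Tcf7 (-1.61, SE 0.42, against -1.64, SE 0.46, adjusted p = 0.052) and Ifng (0.61, SE 0.17, against 0.49, SE 0.17, adjusted p = 0.10). The SE of Tcf7 grew, and the change of Ifng shrank.

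Leaving out 1 of the 10 libraries ended the call of Tcf7 (4 of 10, adjusted p up to 0.081, without Pembrolizumab 1), Cd83 (2 of 10, adjusted p up to 0.053, without Control 2), Slamf6 (3 of 10, adjusted p up to 0.061, without Control 4) and Ifng (7 of 10, adjusted p up to 0.095, without Control 1), where the count is of libraries whose absence ended it. Of the 4 genes of the inhibitory receptor and exhaustion list that passed, it ended Lag3 (1 of 10, adjusted p up to 0.051, without Pembrolizumab 3) and Bhlhe40 (10 of 10, adjusted p up to 0.11, without Control 1). Among lists it ended the calls of TNF receptor and NF-kB targets (5 of 10, adjusted p up to 0.12, without Pembrolizumab 2), oxidative phosphorylation (1 of 10, adjusted p up to 0.057, without Pembrolizumab 2), fatty acid oxidation and lipid uptake (3 of 10, adjusted p up to 0.11, without Pembrolizumab 2) and fibroblasts and stroma (1 of 10, adjusted p up to 0.051, without Control 1). Without a filter 12 of the 16 largest changes passed. The named genes lost, with adjusted p, were Gzmf (0.052), Tcf7 (0.095), Cd74 (0.056), Cd83 (0.065), Slamf6 (0.062), S1pr1 (0.052), Ifng (0.10), Lag3 (0.054) and Bhlhe40 (0.12). Without Control 1 and ABL503 3 they were Tcf7 (0.069) and Ifng (0.091). Ifng was also lost with only the groups compared, after quantile normalization and after rescaling to equal sums (adjusted p = 0.073, 0.099 and 0.0505). Bhlhe40 was lost after quantile normalization (0.074), with the replicate number as a block (0.064) and after rescaling (0.05002). It was lost with the immediate early covariate too (0.051). The other-cell covariate ended Lag3 (0.054) and Bhlhe40 (0.063). The count of changed genes was 421 without Control 1 and 383 without Pembrolizumab 1.

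ABL503 against Control asked what the bispecific antibody alone changed. The changed genes were mostly higher, and 4 fell. Il1r2, the decoy receptor for interleukin 1, rose from 53.7 ± 17 to 389.8 ± 108 FPKM (log2 change 2.85, SE 0.39, adjusted p = 0.0019), and Gzmc, granzyme C, from 48.1 ± 67 to 387 ± 83.3 (log2 change 3.81, SE 0.63, adjusted p = 0.0048). Tnfsf4, the gene of OX40 ligand, rose from 5.002 ± 2.46 to 24.6 ± 5.08 (log2 change 2.22, SE 0.29, adjusted p = 0.0014) and Tnfrsf9 from 107 ± 13.6 to 163 ± 15.8 (log2 change 0.60, SE 0.12, adjusted p = 0.014). Gzmb and Prf1 did not pass, at 0.72 (SE 0.20, adjusted p = 0.13) and 0.84 (SE 0.21, adjusted p = 0.075).

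Of 11794 genes 73 passed, 69 higher and 4 lower. Beside Il1r2, Gzmc and Tnfsf4, the largest rises at a mean log2(FPKM + 1) of at least 3 were Gzmf (3.32, adjusted p = 0.036), Serpine2 (2.45), the trefoil peptide gene Tff1 (2.05), Hsph1, a heat-shock protein of the HSP110 family (1.64), and Zbtb32 (1.51). The 3 named falls were Rgs10, a regulator of G-protein signalling (-1.05, SE 0.22, adjusted p = 0.032), Flt3l, a growth factor for dendritic cells (-0.74, SE 0.15, adjusted p = 0.019), and Gimap6, a GTPase of lymphocytes (-0.48, SE 0.09, adjusted p = 0.011). The remaining fall was the uncharacterised LOC115488275 (-1.56, SE 0.34, adjusted p = 0.036), named after its value was seen. Costimulatory receptors and ligands were higher as a list (median log2 change 0.27, camera adjusted p = 0.00075, and adjusted p = 0.10 with an estimated correlation). Of 17 tested, 3 rose and 0 fell, or 5 and 0 adjusted over the list alone. The 3 were Tnfsf4, Tnfrsf9 and Cd70, the CD27 ligand (2.84, SE 0.46, adjusted p = 0.0037).

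Of the 36 lists, 14 passed camera at the preset correlation in ABL503, and none of them with an estimated one. Glycolysis and hypoxia genes were higher (median log2 change 0.18, camera adjusted p = 2.09e-06, and adjusted p = 0.11 with an estimated correlation). Of 25 tested, 2 rose and 0 fell, or 7 and 0 adjusted over the list alone. Cytotoxic effector molecules were higher (median log2 change 0.30, camera adjusted p = 5.63e-06, and adjusted p = 0.10 with an estimated correlation). Of 19 tested, 2 rose and 0 fell, or 9 and 1 adjusted over the list alone. Effector cytokines and chemokines were higher (median log2 change 0.29, camera adjusted p = 0.00036, and adjusted p = 0.11 with an estimated correlation). Of 15 tested, 1 rose and 0 fell, or 4 and 0 adjusted over the list alone. Cholesterol synthesis genes were higher (median log2 change 0.32, camera adjusted p = 9.08e-06, and adjusted p = 0.10 with an estimated correlation). Of 19 tested, 1 rose and 0 fell, or 3 and 0 adjusted over the list alone. Idi1, an isomerase of the sterol pathway, gave 0.93 (SE 0.20, adjusted p = 0.032). Type I interferon response genes were lower (median log2 change -0.31, camera adjusted p = 2.09e-06, and adjusted p = 0.10 with an estimated correlation). Of 26 tested, 0 rose and 0 fell, or 0 and 4 adjusted over the list alone. Ifit3b had the smallest p among them, at -0.76 (SE 0.18, adjusted p = 0.064).

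The dissociation-stress list rose in part after ABL503 (median log2 change 0.10, camera adjusted p = 0.0084, and adjusted p = 0.36 with an estimated correlation). Of 18 tested, 5 rose and 0 fell, or 6 and 3 adjusted over the list alone. The 5 that rose were heat-shock genes. Hspa1a, which is outside the rule for named genes, changed by 1.80 (SE 0.33, adjusted p = 0.011) and Hspa1b by 1.82. Hsph1, Hsp90aa1 (0.63) and Hspa8 (0.58) were the others. Markers of CD4 and regulatory T cells were higher as a list (median log2 change 0.39, camera adjusted p = 0.043, and adjusted p = 0.29 with an estimated correlation), as were mitochondrially encoded genes (median log2 change 0.15, camera adjusted p = 0.022, and adjusted p = 0.57 with an estimated correlation), while ribosomal protein genes were lower (median log2 change -0.11, camera adjusted p = 0.0013, and adjusted p = 0.51 with an estimated correlation). None of the members of these 3 lists passed, adjusted over all genes or over the list alone. Stem-like genes were lower as a list (median log2 change -0.27, camera adjusted p = 0.0013, and adjusted p = 0.36 with an estimated correlation). Havcr2 gave 0.67 (SE 0.15, adjusted p = 0.039), Ifng 0.45 (SE 0.17, adjusted p = 0.28), Tcf7 -0.56 (SE 0.42, adjusted p = 0.65) and Mki67 0.15 (SE 0.17, adjusted p = 0.81).

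Leaving out 1 of the 10 libraries ended the call of Gzmf (9 of 10, adjusted p up to 0.10, without Control 4), Rgs10 (7 of 10, adjusted p up to 0.087, without Control 2), Flt3l (5 of 10, adjusted p up to 0.061, without Control 2), LOC115488275 (8 of 10, adjusted p up to 0.11, without ABL503 5), Tnfrsf9 (1 of 10, adjusted p up to 0.054, without ABL503 5), Idi1 (8 of 10, adjusted p up to 0.10, without ABL503 3) and Havcr2 (9 of 10, adjusted p up to 0.091, without ABL503 3). The 2 glycolysis genes and the 1 cytokine gene that rose depended on single libraries too: Slc2a3 (8 of 10, adjusted p up to 0.097, without ABL503 1), Pgk1 (9 of 10, adjusted p up to 0.10, without ABL503 1) and Ccl3 (9 of 10, adjusted p up to 0.14, without Control 1). Among lists it ended the calls of dissociation-stress immediate early (2 of 10, adjusted p up to 0.20, without ABL503 3), ribosomal proteins (1 of 10, adjusted p up to 0.13, without Control 1), mitochondrially encoded (4 of 10, adjusted p up to 0.72, without Control 1) and cD4 and regulatory T cells (7 of 10, adjusted p up to 0.091, without Control 1).

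Without a filter 7 of the 11 largest changes in ABL503 against Control passed. The named genes lost, with adjusted p, were Gzmf (0.14), Serpine2 (0.056), Rgs10 (0.12), Flt3l (0.068), LOC115488275 (0.13), Idi1 (0.11), Havcr2 (0.12), Hspa1a (0.053), Slc2a3 (0.10), Pgk1 (0.11) and Ccl3 (0.17). Without Control 1 and ABL503 3, the libraries with the lowest array weights, left out after the data were seen, they were Gzmf (0.14), Rgs10 (0.15), LOC115488275 (0.22), Idi1 (0.22), Havcr2 (0.15), Hspa1a (0.058), Slc2a3 (0.17), Pgk1 (0.15) and Ccl3 (0.26). With only the groups compared they were Flt3l (0.063), LOC115488275 (0.06), Havcr2 (0.10), Slc2a3 (0.051) and Ccl3 (0.12), and with the replicate number as a block Gzmf (0.067) and Havcr2 (0.077). Array weights ended LOC115488275 (0.058) and Pgk1 (0.058), and the immediate early covariate Rgs10 (0.073), Idi1 (0.073), Havcr2 (0.079), Slc2a3 (0.077), Pgk1 (0.077) and Ccl3 (0.074). The count of changed genes was 46 without ABL503 3, 40 without ABL503 5, and 37 without Control 1 and ABL503 3.

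The Combination against Control asked what both antibodies together changed. Cytotoxic and glycolysis genes were higher as lists. Stem-like, naive and memory genes were lower, though not with an estimated correlation (adjusted p = 0.21). Prf1 rose to 28.5 ± 4.88 FPKM (log2 change 2.06, SE 0.21, adjusted p = 9.42e-06) and Gzmb to 2122 ± 686 (log2 change 1.73, SE 0.20, adjusted p = 2.83e-05). Aldoa rose from 506 ± 69.1 to 1096 ± 85.8 FPKM (log2 change 1.12, SE 0.10, adjusted p = 4.25e-06), while Id3 fell from 140.4 ± 49.95 to 34.7 ± 17.7 (log2 change -2.06, SE 0.27, adjusted p = 7.19e-05) and Tcf7 to 9.49 ± 5.88 (log2 change -2.0, SE 0.42, adjusted p = 0.0041). Tnfrsf9 rose to 259 ± 35.5 FPKM (log2 change 1.26, SE 0.12, adjusted p = 4.25e-06).

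**Figure D2:**
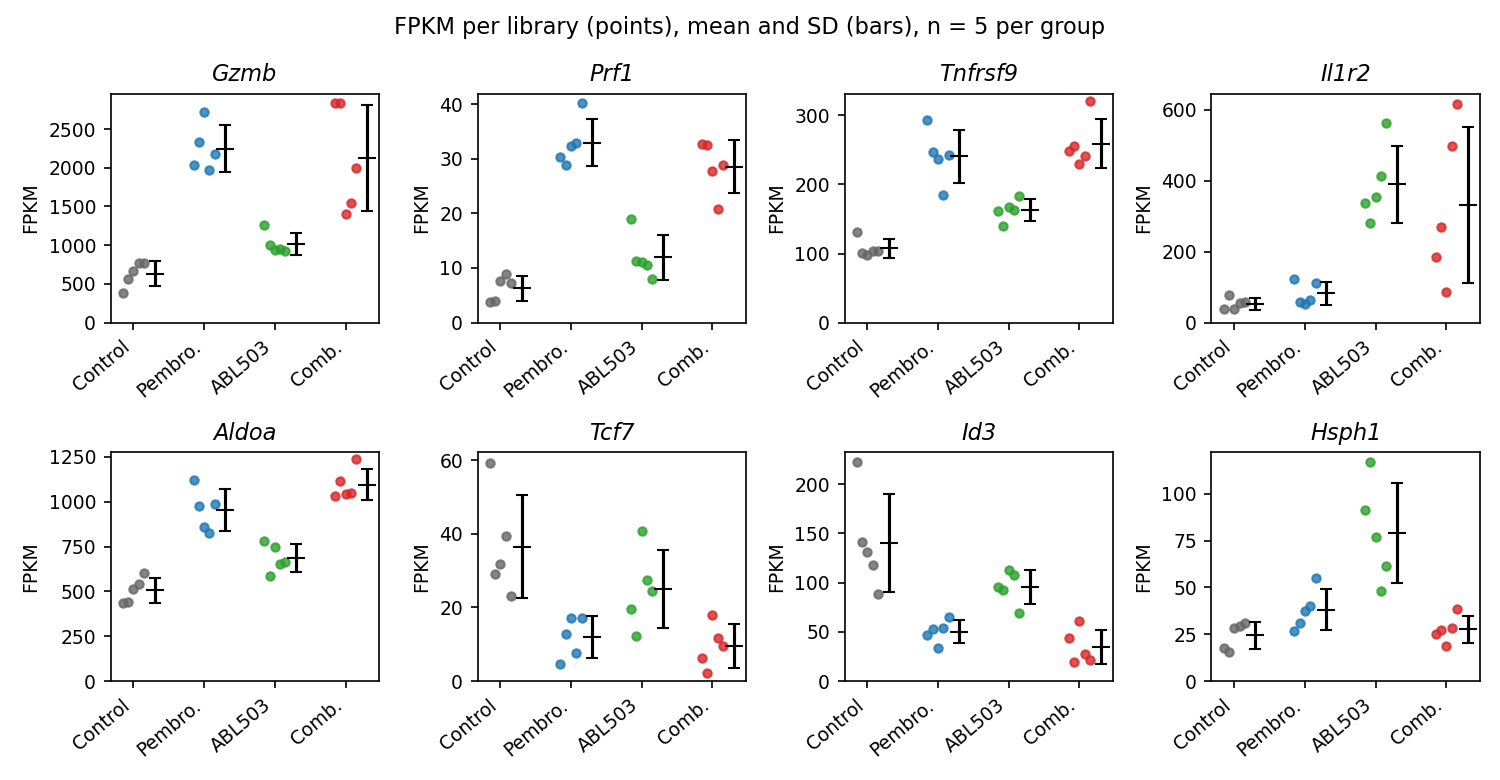
FPKM (linear y axis from 0) of 8 genes in each of the 20 libraries, points coloured by group, with the mean and SD of the 5 libraries beside them. Prf1 lay between 3.83 and 8.83 FPKM in Control and between 28.9 and 40.2 in Pembrolizumab, and Hsph1 between 48.3 and 117 in ABL503 and between 15.6 and 30.8 in Control. These 8 genes were chosen for display after the values were seen.

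Of 11794 genes 1484 passed, 748 higher and 736 lower. The largest rises at a mean log2(FPKM + 1) of at least 3 were Serpine2 (4.63), Gzmf (3.64), Gzmc (3.58) and Ly6a2 of the Ly6 surface protein family (2.93). Next were Bnip3 (2.40), Il1r2 (2.34), Prf1 and Zbtb32 (1.78). The largest falls above that limit were the MHC class II genes H2-Aa (-2.57) and H2-Ab1 (-1.87), Ly6d (-2.47) and Tyrobp, an adaptor of myeloid and NK receptors (-2.09). The others were Id3, Tcf7, Cd7 (-1.99) and Cd74 (-1.91). Adjusted p over these 16 ran from 6.41e-06 for Serpine2 to 0.015 for H2-Ab1.

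Glycolysis and hypoxia genes rose in the Combination (median log2 change 0.60, camera adjusted p = 1.30e-13, and adjusted p = 0.027 with an estimated correlation). Of 25 tested, 15 rose and 0 fell, or 15 and 0 adjusted over the list alone. Tpi1, triose phosphate isomerase, changed by 1.33 (SE 0.15, adjusted p = 2.83e-05) and Pgk1 by 1.01 (SE 0.12, adjusted p = 2.83e-05). Cytotoxic effector molecules rose (median log2 change 0.60, camera adjusted p = 3.60e-07, and adjusted p = 0.027 with an estimated correlation). Of 19 tested, 10 rose and 1 fell, or 12 and 1 adjusted over the list alone. Gzme, granzyme E, at a lower level, gave 3.06 (SE 0.52, adjusted p = 0.00088). Stem-like, naive and memory genes fell (median log2 change -0.61, camera adjusted p = 1.51e-07, and adjusted p = 0.21 with an estimated correlation). Of 25 tested, 1 rose and 11 fell, or 1 and 14 adjusted over the list alone. The quiescence factor Klf2 changed by -1.17 (SE 0.23, adjusted p = 0.003), Klf3 by -1.58 (SE 0.23, adjusted p = 0.00023) and S1pr1 by -1.43 (SE 0.22, adjusted p = 0.00041). Il7r, the interleukin 7 receptor, changed by -0.72 (SE 0.20, adjusted p = 0.024).

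Effector genes were higher in the Combination (median log2 change 0.38, camera adjusted p = 0.00037, and adjusted p = 0.051 with an estimated correlation). Of 20 tested, 6 rose and 1 fell, or 10 and 1 adjusted over the list alone. The chemokine receptor Ccr2 gave 1.26 (SE 0.20, adjusted p = 0.00037). Fatty acid oxidation genes were higher (median log2 change 0.35, camera adjusted p = 0.00013, and adjusted p = 0.051 with an estimated correlation). Of 14 tested, 4 rose and 0 fell, or 7 and 0 adjusted over the list alone. Acadl, an acyl-CoA dehydrogenase, gave 0.46 (SE 0.10, adjusted p = 0.0068). Oxidative phosphorylation genes were higher (median log2 change 0.21, camera adjusted p = 4.76e-05, and adjusted p = 0.47 with an estimated correlation). Of 28 tested, 8 rose and 0 fell, or 10 and 1 adjusted over the list alone. Sdha of complex II gave 0.58 (SE 0.15, adjusted p = 0.016). Mitosis genes were higher as a list (median log2 change 0.33, camera adjusted p = 0.0002, and adjusted p = 0.47 with an estimated correlation). Of 29 tested, 2 rose and 0 fell, or 2 and 0 adjusted over the list alone. Mki67 itself gave 0.17 (SE 0.17, adjusted p = 0.53). TNF receptor and NF-kB targets were lower (median log2 change -0.21, camera adjusted p = 0.0046, and adjusted p = 0.47 with an estimated correlation). Of 24 tested, 0 rose and 5 fell, or 0 and 9 adjusted over the list alone. Tnip1, an inhibitor of that pathway, gave -0.59 (SE 0.14, adjusted p = 0.0074). Ribosomal protein genes were lower (median log2 change -0.19, camera adjusted p = 2.98e-05, and adjusted p = 0.47 with an estimated correlation). Inhibitory receptor genes were higher (median log2 change 0.25, camera adjusted p = 0.027, and adjusted p = 0.47 with an estimated correlation), with Havcr2 at 0.71 (SE 0.15, adjusted p = 0.0041) and Pdcd1 at 0.80 (SE 0.24, adjusted p = 0.03).

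Markers of other cells moved with these groups. Macrophage and monocyte genes were lower (median log2 change -0.84, camera adjusted p = 0.0093, and adjusted p = 0.47 with an estimated correlation). Of 13 tested, 0 rose and 3 fell, or 0 and 3 adjusted over the list alone. Tyrobp and Fcer1g (-1.45, SE 0.37, adjusted p = 0.015) were among them. B and plasma cell genes were lower (median log2 change -0.82, camera adjusted p = 0.042, and adjusted p = 0.31 with an estimated correlation), with the immunoglobulin gene Ighm at -1.24 (SE 0.22, adjusted p = 0.0014). Of 9 dendritic-cell and antigen-presentation genes 4 fell and 1 rose (adjusted p = 0.24). With the mean level of these markers as a covariate, an alternative added after the data were seen, 267 genes passed. Of the 16 largest changes 7 did. The calls of Tcf7 (-2.0, SE 0.42, against -2.07, SE 0.61, adjusted p = 0.078) and Gzmf (3.64, SE 0.72, against 3.92, SE 1.06, adjusted p = 0.057) ended as the SE grew, where values are the log2 change without and with the covariate. Those of H2-Aa (-2.57, SE 0.57, against -0.87, SE 0.64, adjusted p = 0.50), Tyrobp (-2.09, SE 0.43, against -0.65, SE 0.44, adjusted p = 0.46), Gzmc (3.58, SE 0.63, against 2.33, SE 0.83, adjusted p = 0.14) and Il1r2 (2.34, SE 0.39, against 1.64, SE 0.54, adjusted p = 0.11) ended as the change shrank as well. H2-Ab1, Cd74 and Ly6d did not pass either. H2-Aa, Tyrobp and Cd74 are themselves among the markers averaged into the covariate, as are Ighm and Fcer1g below. A smaller change of such genes follows from that, so their lost calls say nothing about carry-over. Outside these 16, Klf2, Klf3, Il7r, Havcr2, Pdcd1, Cd8a, Acadl, Tnip1, Ighm and Fcer1g lost their calls, at adjusted p from 0.057 for Klf3 to 0.79 for Fcer1g. The glycolysis, cytotoxic and stem-like lists passed camera with that covariate, at medians of 0.68, 0.74 and -0.42.

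Leaving out 1 of the 10 libraries ended the call of Il7r (5 of 10, adjusted p up to 0.068, without Control 1) and Pdcd1 (6 of 10, adjusted p up to 0.092, without Control 1). Of the genes behind the fatty acid, mitosis, NF-kB and macrophage counts, it ended Acaa2 (8 of 10, adjusted p up to 0.10, without Control 4), Cenpf (3 of 10, adjusted p up to 0.062, without Combination 2), Rel (3 of 10, adjusted p up to 0.057, without Combination 2), Cd83 (1 of 10, adjusted p up to 0.059, without Control 2), Map3k14 (1 of 10, adjusted p up to 0.058, without Combination 5) and Cybb (6 of 10, adjusted p up to 0.11, without Control 1). Among lists it ended the calls of inhibitory receptors and exhaustion (2 of 10, adjusted p up to 0.067, without Combination 2), macrophages and monocytes (1 of 10, adjusted p up to 0.078, without Control 3) and B and plasma cells (4 of 10, adjusted p up to 0.079, without Control 3). It also ended that of S phase and DNA replication, a list not described above (2 of 10, adjusted p up to 0.15, without Combination 2). Without a filter 15 of the 16 largest changes passed. The named genes lost, with adjusted p, were H2-Ab1 (0.057), Fcer1g (0.057), Il7r (0.076), Pdcd1 (0.098), Acaa2 (0.10), Cd83 (0.068) and Cybb (0.12). With only the groups compared they were Cd8a (0.066), Fcer1g (0.052), Il7r (0.078), Pdcd1 (0.079), Cd83 (0.053), Cenpf (0.081) and Cybb (0.078). Without Control 1 and ABL503 3 they were Fcer1g (0.051), Il7r (0.072), Pdcd1 (0.097) and Cybb (0.091). The count was 958 without Combination 2.

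**Figure D3:**
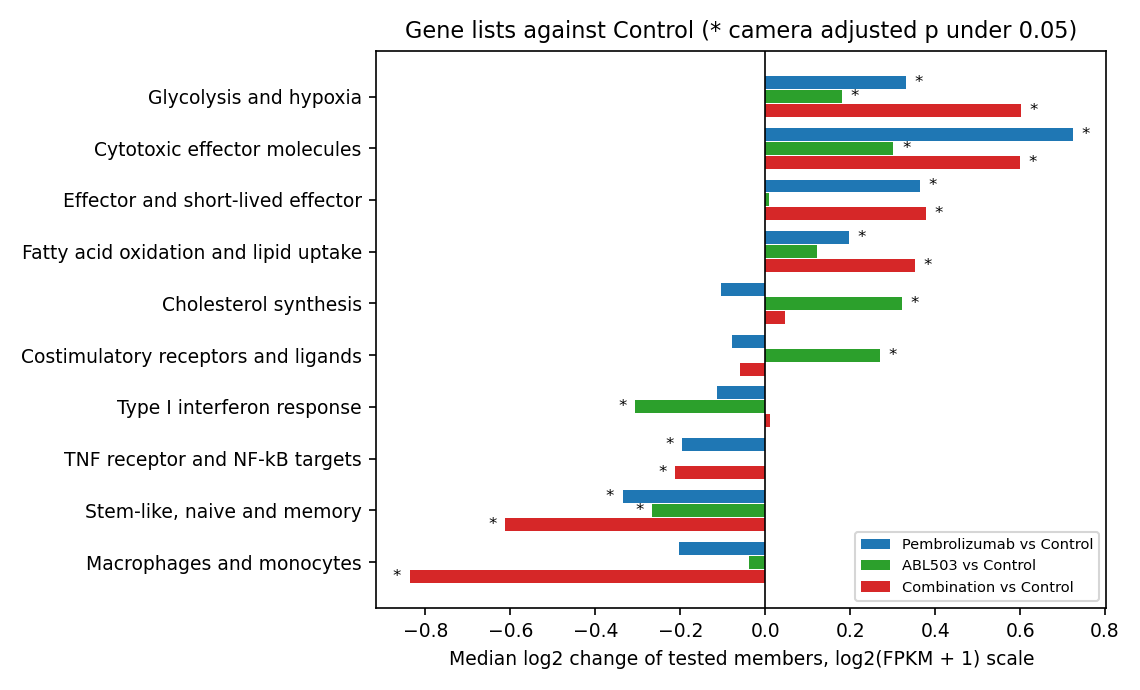
Median log2 change of the tested members of 10 gene lists (x axis, log2(FPKM + 1) scale) in the 3 treated groups against Control, with an asterisk where camera at its preset correlation gave an adjusted p under 0.05. The glycolysis median was 0.33 in Pembrolizumab, 0.18 in ABL503 and 0.60 in the Combination, and the stem-like median -0.34, -0.27 and -0.61.

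Fold changes of the 3 treated groups against the same 5 Control libraries were correlated across genes, and genes are not independent replicates. Pembrolizumab and the Combination shared 227 genes that rose in both and 197 that fell in both, where independent lists of these sizes would share 20.7 and 20.5. That expectation leaves out the shared Control libraries. Their fold changes correlated at r = 0.706, against a median of 0.505 and a highest of 0.9 in 100 simulations of unchanged groups that share a control. The simulations had a median of 0 shared calls, but unchanged groups give few calls at all, so this does not bear on the overlap. The covariance was 0.102 against a simulated 0.0285. With the controls split 2 against 3, so that no Control library was shared, the median r was 0.417. The median shared calls were then 70.5 rises and 26.5 falls, with fewer Control libraries behind each comparison. ABL503 and the Combination shared 43 rises and 3 falls (expected 4.38 and 0.25). Their r was 0.554 (simulated median 0.518, highest 0.833), with a covariance of 0.0679 against a simulated 0.0292, and a split r of 0.253. The split gave a median of 7 shared rises and 0 shared falls. Pembrolizumab and ABL503 shared 33 rises and 2 falls (expected 1.91 and 0.111). Their r was 0.58 (simulated median 0.497, highest 0.859), with a covariance of 0.0584 against a simulated 0.0276, and a split r of 0.22. Here the split medians were 3 shared rises and 0 shared falls.

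**Figure D4:**
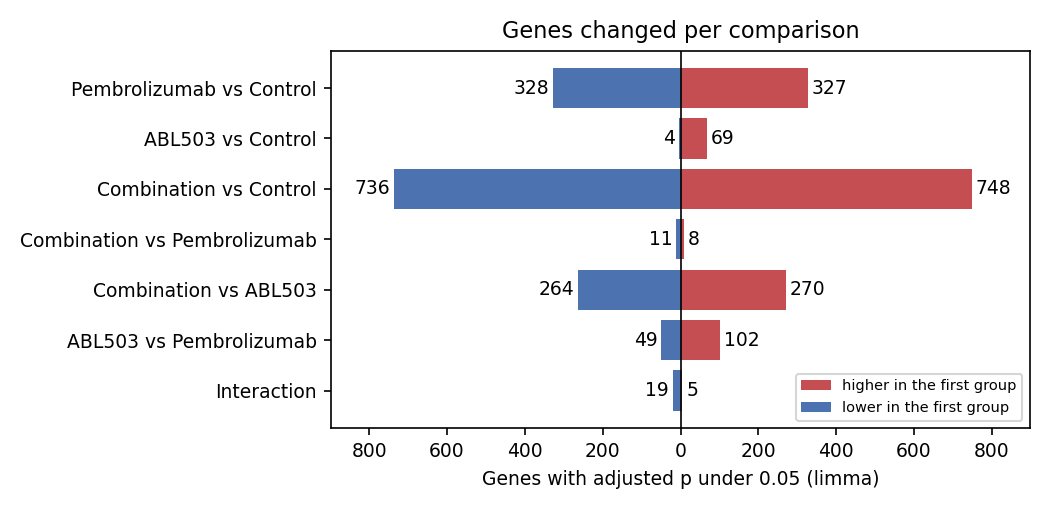
Number of genes past an adjusted p of 0.05 in limma (x axis), higher to the right and lower to the left, for the 7 comparisons. Combination against Control gave 1484 genes and Combination against Pembrolizumab 19.

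ABL503 against Pembrolizumab compared the single treatments directly. Of the cytotoxic effector molecules Gzma, Prf1 and Gzmb fell. Gzma stood at 215 ± 142 FPKM against 801 ± 247 (log2 change -2.02, SE 0.34, adjusted p = 0.0055), and Prf1 changed by -1.43 (SE 0.21, adjusted p = 0.0045) and Gzmb by -1.14 (SE 0.20, adjusted p = 0.0061). Il1r2 (2.28, SE 0.39, adjusted p = 0.0061), Tff1 (2.26), Tnfsf4 (1.83), the activation marker Cd83 (1.79) and Cd74 (1.53) stood higher. Of 11794 genes 151 passed, 102 higher and 49 lower. Cytotoxic effector molecules were lower as a list (median log2 change -0.09, camera adjusted p = 0.0098, and adjusted p = 0.32 with an estimated correlation). Of 19 tested, 0 rose and 3 fell, or 1 and 4 adjusted over the list alone. Cholesterol synthesis genes were higher (median log2 change 0.35, camera adjusted p = 2.63e-08, and adjusted p = 0.021 with an estimated correlation). Of 19 tested, 3 rose and 0 fell, or 11 and 0 adjusted over the list alone. Idi1 gave 0.97 (SE 0.20, adjusted p = 0.018) and Fdps, farnesyl diphosphate synthase, 1.06 (SE 0.24, adjusted p = 0.034). Effector and short-lived effector genes were lower (median log2 change -0.25, camera adjusted p = 5.12e-07, and adjusted p = 0.013 with an estimated correlation). Of 20 tested, 0 rose and 3 fell, or 0 and 9 adjusted over the list alone. Gzma, Ly6c1 (-0.77, SE 0.16, adjusted p = 0.021) and Ly6c2 were the 3. Costimulatory genes went both ways (median log2 change 0.31, camera adjusted p = 0.011, and adjusted p = 0.32 with an estimated correlation). Of 17 tested, 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. Tnfsf11, the gene of RANKL, gave 1.68 (SE 0.31, adjusted p = 0.012), Cd70 2.32 (SE 0.46, adjusted p = 0.015) and Tnfrsf9 -0.55 (SE 0.12, adjusted p = 0.02). Glycolysis genes were lower (median log2 change -0.20, camera adjusted p = 0.00023, and adjusted p = 0.32 with an estimated correlation), and dendritic-cell and antigen-presentation genes higher (median log2 change 0.72, camera adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation).

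Quantile normalization moved the share of higher genes in ABL503 against Pembrolizumab from 67.5% to 57.5%, and rescaling to equal sums moved it the other way, to 77.4%. The count was 54 without ABL503 2, 76 without ABL503 3, 78 without ABL503 4, 82 without ABL503 5, 73 without Pembrolizumab 1, 87 without Pembrolizumab 3 and 80 without Pembrolizumab 4. Leaving out 1 of the 10 libraries ended the calls of Cd74 (4 of 10, adjusted p up to 0.073, without ABL503 2), Idi1 (3 of 10, adjusted p up to 0.059, without ABL503 3), Fdps (7 of 10, adjusted p up to 0.088, without ABL503 3), Cyp51 (8 of 10, adjusted p up to 0.11, without ABL503 2), Ly6c1 (5 of 10, adjusted p up to 0.065, without ABL503 2), Ly6c2 (5 of 10, adjusted p up to 0.072, without ABL503 2) and Tnfrsf9 (2 of 10, adjusted p up to 0.07, without ABL503 2). Among the lists described here it ended those of cytotoxic effector molecules (1 of 10, adjusted p up to 0.052, without ABL503 3) and dendritic cells and antigen presentation (1 of 10, adjusted p up to 0.056, without ABL503 2). Among lists not described here, it ended those of oxidative phosphorylation (3 of 10, up to 0.24), fibroblasts and stroma (5 of 10, up to 0.082), type I interferon response (1 of 10, up to 0.075) and dissociation stress (1 of 10, up to 0.052). Of the 16 largest changes by the rule for named genes, 8 passed without a filter and 10 without Control 1 and ABL503 3. The named genes lost without a filter, with adjusted p, were Cd70 (0.057), Cd74 (0.081), Fdps (0.11), Idi1 (0.06), Cyp51 (0.095), Ly6c1 (0.07), Ly6c2 (0.081) and Tnfrsf9 (0.06). Without Control 1 and ABL503 3 they were Cd74 (0.063), Fdps (0.081), Idi1 (0.058), Cyp51 (0.096), Ly6c1 (0.065) and Ly6c2 (0.063), with only the groups compared Ly6c1 (0.058), Ly6c2 (0.063) and Cyp51 (0.056), and after quantile normalization Ly6c2 (0.08) and Cyp51 (0.053). With the other-cell covariate 12 of the 16 passed, and Cd74, itself part of that covariate, did not (adjusted p = 0.054).

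The Combination against ABL503 asked what pembrolizumab added. Prf1 (1.22, SE 0.21, adjusted p = 0.0026), Gzmb (1.01, SE 0.20, adjusted p = 0.0059) and Tnfrsf9 (0.66, SE 0.12, adjusted p = 0.003) were higher in the Combination, and Hsph1 (-1.45, SE 0.24, adjusted p = 0.0023) and Id3 (-1.55, SE 0.27, adjusted p = 0.003) lower. Of 11794 genes 534 passed, 270 higher and 264 lower. Ly6a2 (2.46), Serpine2 (2.19) and Bnip3 (1.44) led the rises at a mean log2(FPKM + 1) of at least 3. H2-Aa (-2.52), Cd74 (-2.02), Cd24a (-1.90) and Cd83 (-1.67) led the falls above that limit. Glycolysis and hypoxia genes rose (median log2 change 0.39, camera adjusted p = 4.19e-09, and adjusted p = 0.11 with an estimated correlation). Of 25 tested, 9 rose and 0 fell, or 11 and 0 adjusted over the list alone. Gpi1, glucose phosphate isomerase, gave 0.56 (SE 0.10, adjusted p = 0.0038). Type I interferon response genes rose (median log2 change 0.28, camera adjusted p = 2.12e-05, and adjusted p = 0.16 with an estimated correlation). Of 26 tested, 7 rose and 0 fell, or 11 and 0 adjusted over the list alone. Among them were Mx1 (0.99, SE 0.18, adjusted p = 0.0043), a transcribed pseudogene in the RefSeq gene models, and the antiviral gene Oas1a (1.07, SE 0.25, adjusted p = 0.016). Stem-like genes fell (median log2 change -0.48, camera adjusted p = 0.00018, and adjusted p = 0.28 with an estimated correlation). Of 25 tested, 1 rose and 6 fell, or 2 and 12 adjusted over the list alone. The homing receptor Ccr7 gave -1.15 (SE 0.24, adjusted p = 0.0092). Genes of the dissociation-stress list fell (median log2 change -0.15, camera adjusted p = 0.0058, and adjusted p = 0.31 with an estimated correlation). Of 18 tested, 1 rose and 7 fell, or 2 and 8 adjusted over the list alone. Hspa8 (-0.55, SE 0.10, adjusted p = 0.0035) and Hsp90aa1 (-0.58, SE 0.10, adjusted p = 0.004) were among the heat-shock genes that fell.

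Markers of other cells moved as well between the Combination and ABL503. Dendritic-cell and antigen-presentation genes were lower (median log2 change -1.08, camera adjusted p = 0.00087, and adjusted p = 0.16 with an estimated correlation). Of 9 tested, 0 rose and 2 fell, or 0 and 4 adjusted over the list alone. H2-Aa and Cd74 were the ones that fell. Macrophage genes were lower (median log2 change -0.79, camera adjusted p = 0.015, and adjusted p = 0.36 with an estimated correlation). Of 13 tested, 0 rose and 0 fell, or 0 and 3 adjusted over the list alone. B and plasma cell genes were lower (median log2 change -1.08, camera adjusted p = 0.025, and adjusted p = 0.21 with an estimated correlation). Of 5 tested, 0 rose and 1 fell, or 0 and 1 adjusted over the list alone. Of the lists described here, leaving out 1 of the 10 libraries ended the calls of dissociation-stress immediate early (1 of 10, adjusted p up to 0.052, without ABL503 3), macrophages and monocytes (1 of 10, adjusted p up to 0.12, without ABL503 1) and B and plasma cells (4 of 10, adjusted p up to 0.098, without ABL503 2). Lists not described here lost theirs too. They were mitosis (1 of 10, up to 0.059), immediate TCR-induced (2 of 10, up to 0.11), interferon-gamma response (1 of 10, up to 0.0503), unfolded protein response (2 of 10, up to 0.081) and ribosomal proteins (3 of 10, up to 0.14). Without a filter 13 of the 16 largest changes passed. Of the genes named here, H2-Aa (0.059) and Oas1a (0.056) were lost, with adjusted p in brackets. With only the groups compared Oas1a (0.056) was lost. The count was 271 without ABL503 2, 351 without ABL503 3, 329 without ABL503 4, 339 without Combination 2 and 355 without Combination 5. Rescaling to equal sums moved the share of higher genes from 50.6% to 39.1%, and quantile normalization moved it the other way, to 55.9%.

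With the other-cell level as a covariate, 53 genes passed in the Combination against ABL503, and 6 of the 16 largest changes did. Values are the log2 change without and with it. The SE grew while the change moved by little for Gzmb (1.01, SE 0.20, against 1.06, SE 0.29, adjusted p = 0.10), Tnfrsf9 (0.66, SE 0.12, against 0.61, SE 0.17, adjusted p = 0.11), Hsph1 (-1.45, SE 0.24, against -1.37, SE 0.35, adjusted p = 0.096), Id3 (-1.55, SE 0.27, against -1.41, SE 0.39, adjusted p = 0.11) and Cd24a (-1.90, SE 0.39, against -1.80, SE 0.57, adjusted p = 0.16), whose calls ended. The change shrank as well for Serpine2 (2.19, SE 0.45, against 1.55, SE 0.62, adjusted p = 0.27), H2-Aa (-2.52, SE 0.57, against -0.87, SE 0.63, adjusted p = 0.58) and Cd74 (-2.02, SE 0.32, against -1.17, SE 0.38, adjusted p = 0.17). H2-Aa and Cd74 are part of the covariate, so a smaller change was built in for them. Mx1, Oas1a, Ccr7 and Gpi1 did not pass either, at adjusted p from 0.1 for Mx1 to 0.17 for Ccr7.

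The Combination against Pembrolizumab asked what ABL503 added, and 19 single genes differed. Lgals9, which encodes galectin-9, rose from 83.4 ± 9.58 to 136 ± 12.7 FPKM (log2 change 0.71, SE 0.10, adjusted p = 0.0019), and Ly6e, a Ly6 family gene, from 534 ± 46 to 926 ± 129.6 (log2 change 0.79, SE 0.11, adjusted p = 0.0019). Ier3, an early response gene, fell from 70.6 ± 9.12 to 33.1 ± 4.49 (log2 change -1.07, SE 0.16, adjusted p = 0.0092). Of 11794 genes 19 passed, 8 higher and 11 lower, against 1552 at an unadjusted p under 0.05. The other named rises were the lymphotoxin gene Ltb (0.69), Tspan13 (0.69), Tspan31 (0.62), Rab8a (0.49) and Stat4, a mediator of interleukin 12 signals (0.47). The other named falls were Tnfsf14, which encodes the ligand LIGHT (-1.16), Lcn4 (-1.15), Ovol2 (-1.10), Cd9 (-0.85), H4c9 (-0.66) and Morrbid (-0.58). Gzmb (-0.13, SE 0.20, adjusted p = 0.81), Prf1 (-0.21, SE 0.21, adjusted p = 0.70), Tcf7 (-0.38, SE 0.42, adjusted p = 0.73) and Tnfrsf9 (0.11, SE 0.12, adjusted p = 0.72) did not pass. Of the 36 lists, 13 passed camera at the preset correlation between the Combination and Pembrolizumab, and none with an estimated one. Stem-like genes were lower (median log2 change -0.28, camera adjusted p = 0.00029, and adjusted p = 0.37 with an estimated correlation), as were immediate TCR-induced genes (median log2 change -0.25, camera adjusted p = 0.00029, and adjusted p = 0.32 with an estimated correlation) and MYC and mTORC1 genes (median log2 change -0.22, camera adjusted p = 0.00037, and adjusted p = 0.32 with an estimated correlation). Glycolysis genes were higher (median log2 change 0.20, camera adjusted p = 0.00043, and adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes were lower as a list (median log2 change -0.22, camera adjusted p = 2.05e-10, and adjusted p = 0.32 with an estimated correlation). Of 28 tested, 0 rose and 0 fell, or 0 and 3 adjusted over the list alone. S-phase genes were higher as a list (median log2 change 0.23, camera adjusted p = 0.00037, and adjusted p = 0.45 with an estimated correlation). Of 30 tested, 0 rose and 0 fell, or 0 and 0 adjusted over the list alone. Macrophage genes had a median of -0.74 (camera adjusted p = 0.0021, and adjusted p = 0.37 with an estimated correlation). Of the 14 named genes, 3 (Ly6e, Lgals9 and Ier3) passed without each library in turn. The call of Ier3 ended without a filter (adjusted p = 0.051) and with the other-cell level as a covariate, where values are the log2 change without and with it: Ier3 (-1.07, SE 0.16, against -1.04, SE 0.20, adjusted p = 0.069). Under each of these settings 2 of the 14, Ly6e and Lgals9, passed. With only the groups compared 3 did, with Ier3, and with the replicate number as a block 8. Quantile normalization ended Stat4 (0.063). The count was 6 without Pembrolizumab 1, 49 without Pembrolizumab 2, 31 without Pembrolizumab 3, 12 without Pembrolizumab 4, 7 without Pembrolizumab 5, 45 without Combination 1, 6 without Combination 2, 7 without Combination 4 and 7 without Combination 5.

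The interaction asked whether pembrolizumab changed genes differently with ABL503 than without it. It was negative for the heat-shock genes Hsph1 (-2.09, SE 0.34, adjusted p = 0.012) and Hspd1 (-1.20, SE 0.19, adjusted p = 0.0088), for Zbtb32 (-2.25, SE 0.33, adjusted p = 0.0046) and for Ier3 (-1.62, SE 0.23, adjusted p = 0.0046). Other genes below 0 were Ms4a4a (-1.63), Ovol2 (-1.63), Hspe1 (-1.43), Stard10 (-1.24) and Hsp90aa1 (-0.75). It was positive for Lgals9 (0.97, SE 0.13, adjusted p = 0.0046), Stat4 (0.75, SE 0.13, adjusted p = 0.023), Limd2 (0.70), Rab8a (0.68) and Mob2 (0.62). Hsph1 stood at 24.4 ± 7.21 FPKM in Control, 38.1 ± 10.9 in Pembrolizumab, 79.1 ± 26.8 in ABL503 and 27.7 ± 7.23 in the Combination. Of 11794 genes 24 passed, 5 above 0 and 19 below 0, against 1210 at an unadjusted p under 0.05. Type I interferon response genes had a positive interaction as a list (median log2 interaction 0.47, camera adjusted p = 8.51e-08, and adjusted p = 0.16 with an estimated correlation). Of 26 tested, 0 passed above 0 and 0 below, or 8 and 0 adjusted over the list alone. Cytotoxic effector molecules had a negative one (median log2 interaction -0.56, camera adjusted p = 0.0006, and adjusted p = 0.16 with an estimated correlation). Of 19 tested, 0 passed above 0 and 0 below, or 1 and 3 adjusted over the list alone. Prf1 gave -1.05 (SE 0.29, adjusted p = 0.15) and Gzmb -0.85 (SE 0.28, adjusted p = 0.24). Costimulatory genes (median log2 interaction -0.38, camera adjusted p = 0.0048, and adjusted p = 0.16 with an estimated correlation) and unfolded-protein-response genes (median log2 interaction -0.25, camera adjusted p = 4.19e-05, and adjusted p = 0.16 with an estimated correlation) were below 0 as well.

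Without a filter 4 of the 13 genes named by size of change passed (Lgals9, Zbtb32, Ier3 and Hspd1), and without Control 1 and ABL503 3 the same 4 and Stat4. Hsph1 lost its call in both, at adjusted p = 0.063 and 0.06. So did Hspe1 (0.12 and 0.069) and Hsp90aa1 (0.11 and 0.069), the last outside those 13. With the other-cell covariate 7 of the 13 passed, Hsph1 among them, and with the replicate number as a block 9, Rab8a (0.082), Mob2 (0.081), Ms4a4a (0.081) and Stard10 (0.082) being lost. Leaving out 1 of the 20 libraries ended the call of Stat4 (2 of 20, adjusted p up to 0.052, without Pembrolizumab 1), Limd2 (6 of 20, adjusted p up to 0.076, without Pembrolizumab 5), Rab8a (13 of 20, adjusted p up to 0.076, without Pembrolizumab 5), Mob2 (12 of 20, adjusted p up to 0.076, without Pembrolizumab 5), Ms4a4a (13 of 20, adjusted p up to 0.082, without Combination 3), Ovol2 (7 of 20, adjusted p up to 0.056, without Control 5), Hspe1 (10 of 20, adjusted p up to 0.076, without Pembrolizumab 5), Stard10 (13 of 20, adjusted p up to 0.076, without Pembrolizumab 5) and Hsp90aa1 (14 of 20, adjusted p up to 0.079, without Combination 3). The count was 12 without Control 3, 10 without Control 5, 11 without ABL503 2, 10 without ABL503 5, 6 without Pembrolizumab 1, 14 without Pembrolizumab 3, 49 without Pembrolizumab 4, 7 without Pembrolizumab 5, 11 without Combination 2, 7 without Combination 3 and 11 without Combination 4.

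On GRCm38, by RefSeq gene models, Gzmb lies on chromosome 14, 56258836 to 56262334 and Prf1 on chromosome 10, 61297751 to 61304684. Tnfrsf9 lies on chromosome 4, 150920155 to 150946104, Tcf7 on chromosome 11, 52246527 to 52283383 and Hsph1 on chromosome 5, 149616843 to 149636498, each value covering the whole gene. Cd274, the PD-L1 gene, gave -0.27 (SE 0.17, adjusted p = 0.40) in Pembrolizumab, -0.08 (SE 0.17, adjusted p = 0.91) in ABL503 and -0.52 (SE 0.17, adjusted p = 0.053) in the Combination, each against Control. Tox, a factor of exhausted T cells, gave -0.49 (SE 0.33, adjusted p = 0.44), -0.11 (SE 0.33, adjusted p = 0.94) and -0.15 (SE 0.33, adjusted p = 0.80). Values of Tnfrsf9, Pdcd1 and Cd274 come from mouse gene models in mice humanised for these genes, and the labels do not say how much mouse sequence each locus kept. Reads of Gzmc, Gzme and Gzmf, of Hspa1a and Hspa1b, and of the Ly6 genes can be shared between near-identical copies, so their split between copies is uncertain.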

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

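All tests of the explanations for the stem-like and heat-shock patterns were chosen after the result was seen. The splits of the libraries, the Dixon test and the interaction were planned.

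Chance as the source of the gene counts was tested by redrawing the groups 100 times per comparison, the real grouping among them. In each of the 7 comparisons 1 grouping of the 100, the real one, gave as many genes. Chance is thus an unlikely source of the counts in the comparisons of 2 groups. For the interaction the labels of all 20 libraries were shuffled, which removes the effects of the single treatments as well. Those draws cannot decide whether the interaction count arose by chance. The real and the highest other count were 655 and 4 for Pembrolizumab against Control, 73 and 19 for ABL503 against Control, 1484 and 467 for the Combination against Control, 19 and 5 for the Combination against Pembrolizumab, 534 and 144 for the Combination against ABL503, 151 and 2 for ABL503 against Pembrolizumab, and 24 and 1 for the interaction.

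Of 428 groups of 5 tested (107 named genes in 4 groups), Dixon's test at a critical value of 0.71 singled out 22, or 5.14%, where chance gives about 1 in 20. Values are FPKM against the range of the other 4 libraries of the group. In Control they were Acadl in Control 2 (30.02 against 38.4 to 40.9), Gzme in Control 1 (1.18 against 0 to 0.0485), H2-Aa in Control 3 (69.6 against 13.1 to 18.2), H2-Ab1 in Control 3 (138 against 31 to 37.3), Ltb in Control 1 (106 against 136 to 142), Ovol2 in Control 2 (11.2 against 4.47 to 5.33), Stard10 in Control 4 (11.2 against 5.95 to 7.16) and Tnfrsf9 in Control 1 (131 against 97.4 to 104). In Pembrolizumab they were Birc3 in Pembrolizumab 4 (26.1 against 18.2 to 19.6), Gzmf in Pembrolizumab 3 (11.2 against 55.6 to 92.2), Ifit3b in Pembrolizumab 2 (2.92 against 3.93 to 4.25), Map3k14 in Pembrolizumab 4 (6.39 against 2.9 to 3.6) and Rel in Pembrolizumab 1 (23.4 against 19.6 to 20.3). In ABL503 they were Col1a1 in ABL503 3 (0.0201 against 0 to 0), Gzmb in ABL503 1 (1266 against 927 to 1007), Gzmc in ABL503 1 (248 against 396 to 473), Lcn4 in ABL503 1 (17.9 against 10.9 to 12), Pgk1 in ABL503 1 (329 against 251 to 258), Rel in ABL503 1 (18.6 against 25.1 to 27.2), Slamf6 in ABL503 1 (32.4 against 39.5 to 41.5) and Tff1 in ABL503 3 (92.6 against 137 to 158). In the Combination it was Tnip1 in Combination 2 (25.7 against 37.7 to 39.6).

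The effect of pembrolizumab differed with and without ABL503, by the interaction term, in the following named genes, as log2 values. Below 0 were Zbtb32 (-2.25, SE 0.33, adjusted p = 0.0046), Hsph1 (-2.09, SE 0.34, adjusted p = 0.012), Ms4a4a (-1.63, SE 0.32, adjusted p = 0.036), Ovol2 (-1.63, SE 0.30, adjusted p = 0.031), Ier3 (-1.62, SE 0.23, adjusted p = 0.0046), Hspe1 (-1.43, SE 0.27, adjusted p = 0.034), Stard10 (-1.24, SE 0.24, adjusted p = 0.034), Hspd1 (-1.20, SE 0.19, adjusted p = 0.0088), Cd9 (-1.20, SE 0.22, adjusted p = 0.031) and Hsp90aa1 (-0.75, SE 0.15, adjusted p = 0.034). Above 0 were Lgals9 (0.97, SE 0.13, adjusted p = 0.0046), Stat4 (0.75, SE 0.13, adjusted p = 0.023), Limd2 (0.70, SE 0.13, adjusted p = 0.033), Rab8a (0.68, SE 0.13, adjusted p = 0.034) and Mob2 (0.62, SE 0.12, adjusted p = 0.034). Without a filter Hsph1 no longer passed (adjusted p = 0.063), nor without Control 1 and ABL503 3 together (0.06), and neither did Cd9 (0.10 and 0.065). Cd9 is outside the rule for this comparison, and its leave-one-out test was added after its value was seen. Leaving out 1 of the 20 libraries ended the calls of Ms4a4a, Ovol2, Hspe1, Stard10, Hsp90aa1, Stat4, Limd2, Rab8a and Mob2, as given above. It ended that of Cd9 too (8 of 20, adjusted p up to 0.056, without Control 5). Median interactions of gene lists past camera at the preset correlation were -0.56 (adjusted p = 0.00033) for effector cytokines and chemokines, -0.56 (adjusted p = 0.0006) for cytotoxic effector molecules, -0.50 (adjusted p = 0.014) for dendritic cells and antigen presentation, -0.38 (adjusted p = 0.0048) for costimulatory genes and -0.33 (adjusted p = 4.19e-05) for MYC and mTORC1 genes. Further medians were -0.27 (adjusted p = 0.0015) for IL-2 and STAT5 targets, -0.25 (adjusted p = 4.19e-05) for the unfolded protein response, -0.23 (adjusted p = 0.014) for inhibitory receptors, -0.23 (adjusted p = 0.00032) for immediate TCR-induced genes, -0.10 (adjusted p = 0.015) for ribosomal proteins and -0.0354 (adjusted p = 0.027) for dissociation stress. Medians above 0 were 0.47 (adjusted p = 8.51e-08) for type I interferon response, 0.22 (adjusted p = 0.0048) for interferon-gamma response and 0.13 (adjusted p = 0.028) for the T-cell receptor complex. Leaving out 1 library ended the list calls of inhibitory receptors and exhaustion (2 of 20, adjusted p up to 0.061, without ABL503 3), ribosomal proteins (6 of 20, adjusted p up to 0.24, without Control 5), dissociation-stress immediate early (6 of 20, adjusted p up to 0.23, without ABL503 3) and T-cell receptor complex and CD8 lineage (6 of 20, adjusted p up to 0.082, without Pembrolizumab 2). Without Control 1 and ABL503 3 together the inhibitory receptor, dissociation-stress and dendritic-cell lists did not pass. With an estimated correlation none passed, the lowest adjusted p being 0.16.

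Stem-like, naive and memory genes were lower in the Combination than in Control, the list mean changing by -0.69 (95% interval -0.96 to -0.42). Carry-over of other cells might bring such transcripts into Control, but with the level of other-cell markers as a covariate the change was -0.52 (95% interval -0.90 to -0.14), which argues against it as the whole source. With that covariate 2 of the 11 genes that fell still passed, as the median SE grew from 0.20 to 0.28, and 21 of 25 members were below 0. Scaling between libraries is also argued against, since at least 10 of the 11 still passed under quantile normalization and under rescaling to equal sums. What stays open is a treatment effect on the T cells, and carry-over as a part of the change.

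Heat-shock genes were higher in ABL503 than in Control, with 5 of 7 chaperones past the threshold and a median log2 change of 0.63. Handling stress during tumour dissociation would raise immediate early genes as well, but the mean log2 level of 11 such genes differed by -0.18, ABL503 minus Control (95% interval -0.58 to 0.23 from the spread between the 10 libraries, and up to 0.12 from that of all 20). Both upper ends lie below 0.32, which is 1/2 of the chaperone median and was set as the bound. This argues against handling stress of that kind. A single deviating library is unlikely as the source, since all 5 still passed without each of the 10 libraries. Without Control 1 and ABL503 3 together Hspa1a no longer passed (adjusted p = 0.058), nor without a filter (0.053), and the other 4 did. What stays open is a treatment effect, or a stress that raises chaperones and not immediate early genes, which was not tested.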

How the results depend on the processing

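The rescaling to equal sums, the removal of Control 1 and ABL503 3 together and both covariates were chosen after seeing the data; the other alternatives were fixed beforehand. For counts of changed genes, a pseudocount of 0.1, quantile normalization, rescaling to equal sums and the replicate block moved no count by more than 1.5 times. In the order Pembrolizumab against Control, ABL503 against Control, Combination against Control, Combination against Pembrolizumab, Combination against ABL503, ABL503 against Pembrolizumab and interaction, the counts were as follows. Without a filter they were 321, 42, 939, 3, 271, 67 and 6, with more genes tested. At an adjusted p under 0.1 they were 1154, 115, 2295, 99, 1063, 314 and 79, by the looser limit. With a minimum absolute log2 change of 1 they were 103, 30, 199, 7, 80, 37 and 12, by the added limit. With the replicate number as a block they were 617, 60, 1387, 17, 512, 120 and 16. Leaving out each library gave 383 to 707, 40 to 72, 958 to 1659, 6 to 49, 271 to 752, 54 to 218 and 6 to 49.

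Array weights gave 85 genes for the Combination against Pembrolizumab, 935 for the Combination against ABL503, 301 for ABL503 against Pembrolizumab and 50 for the interaction. Only the groups compared gave 395 for Pembrolizumab against Control and 3 for the Combination against Pembrolizumab, with fewer libraries behind the spread. Without Control 1 and ABL503 3 the counts were 37 for ABL503 against Control, 32 for the Combination against Pembrolizumab, 89 for ABL503 against Pembrolizumab and 7 for the interaction. The other-cell covariate gave 267 for the Combination against Control, 2 for the Combination against Pembrolizumab and 53 for the Combination against ABL503. The immediate early covariate gave 42 for the Combination against Pembrolizumab, 928 for the Combination against ABL503 and 266 for ABL503 against Pembrolizumab. Except where stated, the cause was not tested.

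Under rescaling to equal sums, 193 genes were higher and 300 lower in the Combination than in ABL503, against 270 and 264, while quantile normalization gave 310 and 245. Under quantile normalization, 73 were higher and 54 lower in ABL503 than in Pembrolizumab, against 102 and 49. No named gene or list past the threshold reversed its direction under any alternative run, and no named gene newly passed in the other direction. The direction of genes that passed in neither run was not compared. Results of named genes include many that had not passed, and these count as kept when they again do not pass. Losses can come only from those that had passed, whose numbers per comparison (40, 23, 56, 14, 48, 31 and 15) are given below. Of the results of named genes, 511 kept their side of the threshold and 0 calls were lost with a pseudocount of 0.1, 496 and 7 under quantile normalization and 502 and 6 after rescaling. The numbers were 426 and 90 without a filter and 408 and 106 with the other-cell covariate. Some of those 106 losses are of genes that are part of that covariate, such as H2-Aa, Tyrobp and Cd74. Of the named genes past the threshold, 30 of 40 passed without each library in turn for Pembrolizumab against Control, 13 of 23 for ABL503 against Control, 42 of 56 for the Combination against Control, 3 of 14 for the Combination against Pembrolizumab, 37 of 48 for the Combination against ABL503, 13 of 31 for ABL503 against Pembrolizumab and 5 of 15 for the interaction. Of 96 list results, 7 passed with an estimated correlation and 41 by fry. Leaving out Control 1 and ABL503 3 together ended 25 of the 96. The other-cell covariate ended 7 of 88 and only the groups compared 5 of 82. The other settings, a single library left out aside, ended 4 or fewer.

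Libraries of the same number were not paired: over 30 pairs of groups and numbers, the correlation of residuals ran from -0.146 to 0.107, and 5 of 20 libraries correlated best with their own number. Not run for lack of counts were DESeq2 and its size factors, voom with sample weights, and both filters on counts. With no depth given, how far sequencing depth limits low genes is unknown.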

Other observations

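The measures of alpha and beta V-segment use and the test of treatment as a narrowing factor were chosen before their results were seen, and the test of cell number after. Receptor segments were outside the rule for named genes. FPKM of a segment reflects both cells and transcripts per cell.

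Use of T-cell receptor beta V segments (35 symbols) was less even in the Combination. The effective number of segments, the exponential of the entropy of their FPKM shares, was 11 ± 0.839 in Control (SD, n = 5) and 5.42 ± 2.997 in the Combination, lower in 5 of 5 libraries than in every Control library. The two-sided exact permutation p was 0.0079, the smallest that 252 splits allow, and 0.024 adjusted over the 3 treated groups. Pembrolizumab stood at 9.16 ± 1.38 (exact p = 0.040, adjusted 0.060) and ABL503 at 10.7 ± 1.25 (exact p = 0.71). The Combination was lower than Pembrolizumab by an exact p of 0.040 (adjusted 0.040) and than ABL503 by an exact p of 0.016 (adjusted 0.032). The leading segment held 58.4% ± 22.8 of Trbv FPKM in the Combination and 29% ± 7.05 in Control (exact p = 0.024, adjusted 0.071). It was Trbv17 at 89.7% in Combination 5 and Trbv13-1 at 71.3% in Combination 2.

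A shift of a few expanded clones in the Combination is a candidate explanation, which predicts uneven alpha segments too. The effective number of Trav segments (128 symbols) was 15.3 ± 12.5 in the Combination and 38.4 ± 9.4 in Control, a difference of -23.2 (exact p = 0.016, adjusted 0.048), as that explanation requires. A narrowing by treatment in general remains open: in 2 of the 3 treated groups (Pembrolizumab and Combination) the number was lower at an unadjusted exact p under 0.05, and after adjustment in the Combination. Fewer cells in the Combination libraries may give the same picture and stay open, because genes above 0 FPKM differed by -409.4 (exact p = 0.11), while genes at 1 FPKM or more differed by -323.6 (exact p = 0.0079, adjusted 0.024). Other values go the other way. In Pembrolizumab genes above 0 FPKM differed by -408.8 from Control (exact p = 0.040, adjusted 0.11), with less narrowing than in the Combination. Combination 5, the least even library at 1.65 effective Trbv segments, had 19224 genes above 0 FPKM, inside the Control range of 18712 to 19303. Combination 3, the most even of its group at 9.59, had 18313. The last 2 are single libraries and the depth is unknown, so fewer cells are not excluded. The number of cells sorted per library is not given, which keeps clone expansion and sampling of few cells from being separated.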
